A study of Arabidopsis thaliana with 15 samples.

How the data were processed

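The samples were root cells of Arabidopsis thaliana, ecotype Columbia, taken from 5 populations with 3 arrays each, 15 arrays in all. Per the labels' protocols, seedlings grew for 5 days and were then kept for 3 h without sulfur before the roots were turned into protoplasts and sorted by fluorescence. The marker line was Pet111 for the columella, pWER::GFP for the epidermis with the lateral root cap, pCOR::GFP for the cortex, pSCR::GFP for the endodermis with the quiescent center and pWOL::GFP for the stele. Arrays of roots on full medium were not analysed here, so the comparisons are between populations and not between media. Nothing in the labels says that the replicates came from separate plantings, so p-values measure the spread between these samples, which may be technical.

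RNA was amplified in 2 cycles and labelled with biotin, per the labels' protocols. The deposited values were signal intensity on a linear scale for 22810 probe sets, made with MAS5 per the submitters' processing notes; its version and scaling target were not given in the sources used here. In the deposited intensity table, each array had a mean of about 250 after the lowest and highest 2% of values were left out (250.022 to 250.029). Array medians ran from 46.1 to 80.9, a ratio of 1.76. Detection calls were not used here, and the number of arrays limits the precision.

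The following steps were computed for this report with R 4.3.3 and limma 3.58.1, and with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 for table handling. Choices of test, filter, gene lists and alternatives were fixed before the data were examined. A rule among them set quantile normalization when array medians differed by more than 1.5 times, and it therefore became the main scaling, with the deposited scaling as an alternative. Values were taken as log2(signal + 16), so that differences are on that scale and understate changes of dim probe sets. The 64 control probe sets were left out, and probe sets had to exceed the 40th percentile of their array on at least 3 arrays, which left 16126. No 2 arrays held identical values in most of their probe sets.

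One linear model with a mean per population was fitted to all 15 arrays with lmFit and eBayes with a variance trend. A moderated F test asked whether the 5 means were equal. For each population, limma then compared its mean with the unweighted mean of the other 4. The 5 differences of a probe set cancel out by construction, so higher values in some populations force lower values in others. P-values were adjusted by the Benjamini-Hochberg method, and a probe set was called at an adjusted p under 0.05 and a log2 difference of at least 1 in size. A probe set was called enriched when it passed both thresholds against each other population separately. Gene lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, and adjusted over all lists and populations. In 11 to 34 of 100 divisions of the arrays into 5 groups, as many fixed lists were called in a population, so a list call alone does not exclude chance. The columella contrast was tried on simulated data with 16126 probe sets. It recovered 78% of 100 changes of log2 1.5 and 99% of 100 changes of log2 3, with 2 false calls. The enriched call recovered 39% and 92%. The simulation drew independent noise for each probe set, raised only these genes and counted false higher calls alone. The real arrays differ in many more probe sets, so these shares need not hold for them.

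Gene names came from the platform annotation and a gene table of assembly TAIR10.1. Of the 22810 probe sets, 13513 had 1 gene symbol, 503 had several and 8794 are unnamed here; 13436 of the first were matched to a locus. The array design's genome build was not given in the sources used here, so no coordinates are given. The 23 gene lists held 269 genes, of which 36 had a named probe set here. No member of the lists for sulfate transporters, epidermis, suberin, phloem, nutrient transporters, photosynthesis and heat shock could be tested. A gene with several probe sets was taken by the one of highest mean.

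Genes were named by a rule. For each population it took the 10 enriched genes of largest difference, the 5 of most negative difference among those called lower, and up to 4 members of each called list and of its own marker lists. It also took up to 6 members of each sulfur list past the F test. The rule always included SULTR1;1, SULTR1;2, APR1, APR2, APR3, SDI1, LSU1, LSU2, SLIM1, WER, SCR and WOL, but none of these had a named probe set here, so the marker line genes could not be used to check the labels. Other members of the fixed lists and of the families are named beside their counts and were chosen after their values were seen. The genes given without both arrays in doubt follow the same rule in that fit.

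The alternatives were the deposited scaling, a pseudocount of 1 or 64, no filter or the 60th percentile, no variance trend, array weights, the replicate number as a block, and leaving out each array in turn. After seeing the data, a fit without the arrays labelled epidermis replicate 2 and stele replicate 1 was added, which tested 15911 probe sets, as were lists of at least 9 named genes that share a symbol prefix, taken as families, and of plastid-encoded genes.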

Results

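Gene expression was measured on Affymetrix arrays in 5 sorted root cell populations, each with 3 arrays, from seedlings kept for 3 h without sulfur. The columella is the gravity-sensing core of the root cap. The epidermis sample also held lateral root cap cells, and the endodermis sample also held the quiescent center, the organizer of the root stem cells. The stele is the central cylinder with the vascular tissue. Median deposited signal per array was lowest in the cortex, at 47.8 ± 1.73 (SD, n = 3), and highest in the stele, at 70.0 ± 11.8 (SD, n = 3).

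How alike the arrays of a population were was examined first. Of 15 arrays, 12 correlated best with an array of their own population, across tested probe sets, which are not independent replicates. The array labelled epidermis replicate 2 instead lay nearest to stele replicate 2 (r = 0.973), whose nearest array it was in turn, and reached only 0.826 with its own population. Stele replicate 1 lay nearest to epidermis replicate 3 (r = 0.965) and reached 0.845 with its own. Without these 2 arrays, correlations ran from 0.947 to 0.984 within populations and from 0.669 to 0.874 between them. Groups were kept as labelled, and counts without both arrays, an alternative chosen after seeing the data, are given beside the counts of each population.

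**Figure D1:**
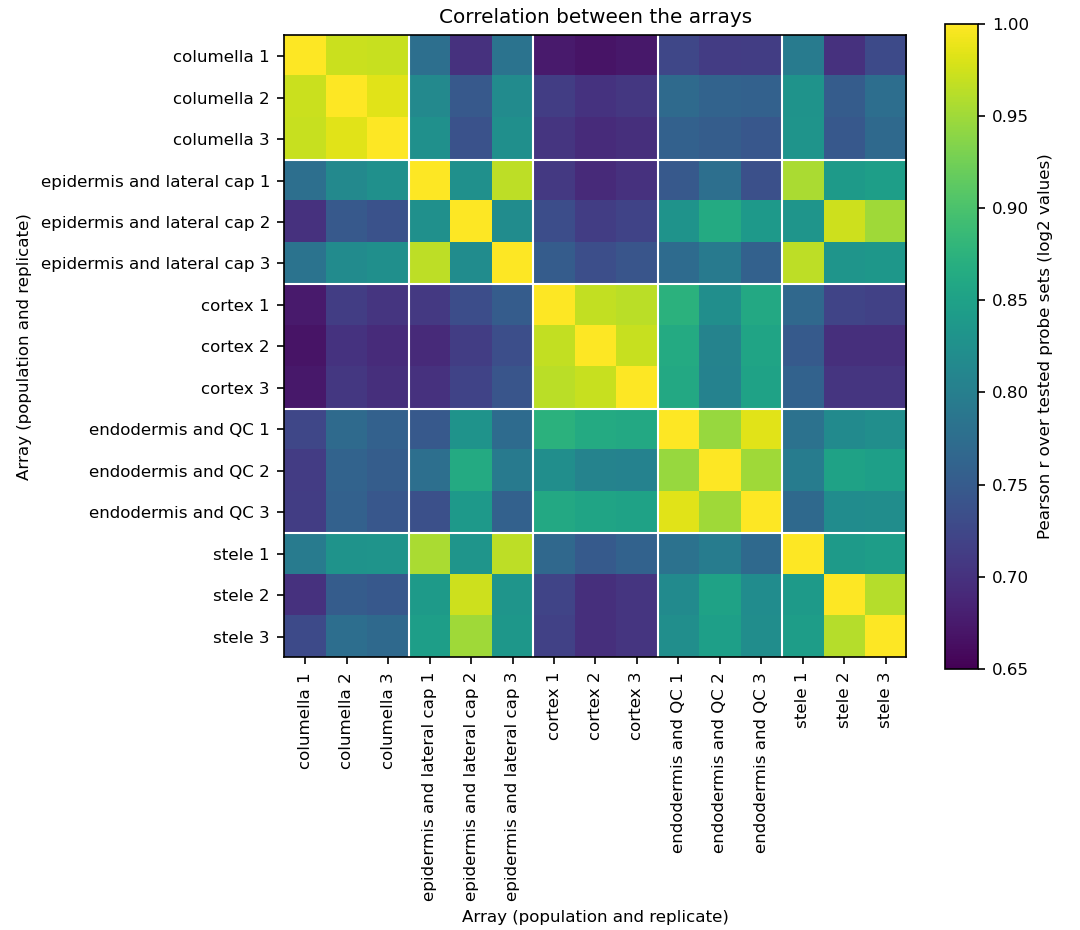
Pearson correlation of log2 values over tested probe sets between each pair of the 15 arrays, ordered by population and replicate, with colour giving r. The array labelled epidermis replicate 2 shares its highest value with stele replicate 2 (0.973), and stele replicate 1 with epidermis replicate 3 (0.965).

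Which transcripts differed among the populations was asked with the F test. Genes of sulfur metabolism were among them. BGLU28, a beta-glucosidase gene known to be induced by sulfur deficiency, had a mean signal of 3862 ± 417 (SD, n = 3) in the endodermis and 24.6 ± 11 (SD, n = 3) in the columella. APS4, a gene for the ATP sulfurylase that activates sulfate, was higher in the cortex by 1.76 ± 0.26 log2 (SE, adjusted p = 9.4e-05) and in the endodermis by 1.58 ± 0.26 (adjusted p = 0.00075). It was lower in the epidermis (-1.28) and the stele (-1.86). SIR, the sulfite reductase gene, was lower in the columella, with a log2 difference of -1.51 ± 0.20 (SE, adjusted p = 4.6e-05).

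The other sulfur genes went different ways. APS3, another ATP sulfurylase gene, was lower in the cortex (-1.30 ± 0.21, SE, adjusted p = 0.00018), where APS4 was higher. CBL, for cystathionine beta-lyase of methionine synthesis, was also lower in the cortex (-1.46 ± 0.26, SE, adjusted p = 0.00042). Without both arrays in doubt, CBL was also called higher in the stele, as was BGLU28, 1 of 2 tested sulfur starvation genes. That BGLU28 call rests on stele replicates 2 and 3, which differ: 11.65 log2 on replicate 2, and within 8.42 to 8.93 on replicate 3. UGT74B1, a glucosyltransferase gene of glucosinolate synthesis, was higher in the cortex (1.41) and the endodermis (1.05) and lower in the epidermis (-1.07). Its call ended in the epidermis without epidermis replicate 1 or 3 (adjusted p = 0.0811 and 0.0884), and in the endodermis without endodermis replicate 1 or 2 (0.0522 and 0.0875) and, at log2 differences of 0.97 and 0.99, without epidermis replicate 3 or stele replicate 1. With a pseudocount of 64 it was under the threshold in both (-0.94 and 0.94), and with array weights in the endodermis (0.95). For SDI2, a relative of a sulfur deficiency gene, the largest gap between population means was 0.70 log2 and the F test gave an adjusted p of 0.33. UGT74C1 was close to background in all populations (F test adjusted p = 0.81). Of 8 tested members of the sulfur lists, 6 passed the F test, and 6 passed adjusted over the list alone; without both arrays in doubt, 6 of 7 passed. As a group, the 3 tested sulfate assimilation genes were not shifted in any population by camera, with adjusted p from 0.0988 in the endodermis to 0.876 in the stele, where the median was 0.23 and the mean -0.29. None of the named sulfate transporters could be tested. In all, 10660 of 16126 probe sets differed among the populations by the F test, and 13224 of 15911 without both arrays in doubt. BGLU28 differed between arrays within the stele and the epidermis as labelled, with a SD of 1.65 and 1.58 log2: it was at 11.65 on stele replicate 2 and 11.31 on epidermis replicate 2, and at 8.42 to 8.93 on the other arrays of both.

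**Figure D2:**
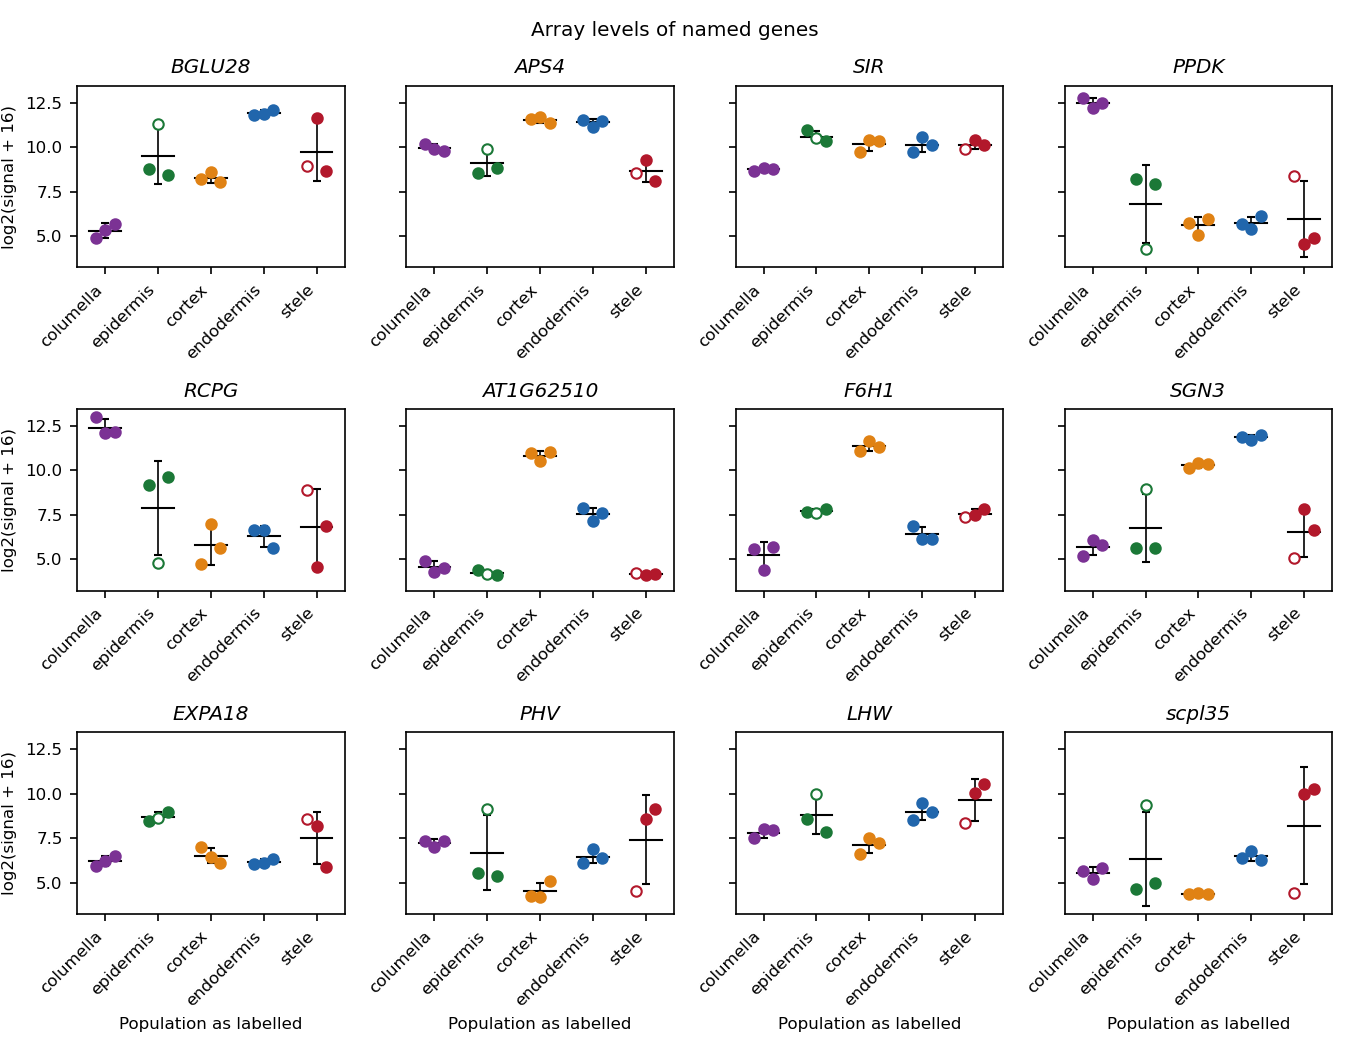
Level of 12 named genes on each array, as log2(signal + 16), by population as labelled; points are arrays, horizontal lines the mean and bars the SD (n = 3), and open points the arrays labelled epidermis replicate 2 and stele replicate 1. BGLU28 has its highest mean in the endodermis and its lowest in the columella, and PHV and scpl35 are high on the open epidermis point and low on the open stele point.

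In the columella, PPDK and AT5G51470 were among the enriched genes of largest difference. PPDK, for pyruvate orthophosphate dikinase, reached a signal of 5765 ± 1127 (SD, n = 3), higher than the mean of the other 4 populations by 6.45 ± 0.76 log2 (SE, adjusted p = 1.3e-05), or 87.6-fold. AT5G51470 and AT1G23160, both of the GH3 family whose known members conjugate amino acids to hormones, were higher by 6.98 ± 1.01 and 5.96 ± 1.14 log2. GH9B6, of a family of cellulase-like enzymes, was higher by 5.88 ± 0.39, and AT1G50060, AT1G26680, AT3G61930, AT1G21340, AT1G48070 and AT4G23590 by 5.84 to 6.77. BGLU28 had the most negative difference (-4.55 ± 0.58, SE), followed by GT72B1, a glucosyltransferase gene (-4.35), AT3G04010 (-4.25), NANA (-4.20) and AT2G20625 (-3.94).

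Among the lists for this population, the single tested root cap marker, RCPG, a root cap polygalacturonase gene, was higher in the columella by 5.72 ± 0.89 log2 (SE, adjusted p = 0.00016). Of 2 tested starch genes, SBE2.2, a starch branching enzyme gene, was higher by 2.62 ± 0.18 (SE), and APL3 had a difference of 0.40. Of 2 wound and touch genes, which protoplasting can induce, ZAT10 was higher by 2.02 and WRKY53 lower (-1.05, but under the threshold at -0.95 without columella replicate 3, -0.98 under the deposited scaling and -0.81 with a pseudocount of 64); adjusted over the list alone, the same counts of 1 each were found. All 4 tested cortex markers and all 3 tested endodermis markers were lower, and both lists were called by camera (adjusted p = 0.00057 and 0.0091); adjusted over the list alone, the counts were again 4 and 3. With an estimated correlation, the cortex list kept an adjusted p of 0.010 and the endodermis list had an adjusted p = 0.10. Because the differences cancel out over the populations, these lower values are in part the counterpart of higher values in the cortex and the endodermis. With a pseudocount of 64, JKD (-0.85) and BLJ (-0.76) of these lists were under the threshold. In total, 1880 probe sets were higher and 1886 lower in the columella, and 932 were enriched. Without both arrays in doubt, the counts were 1958, 2029 and 884, and 845 enriched probe sets were shared.

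In the cortex, AT1G62510 and UGT84A1 were among the enriched genes of largest difference. AT1G62510, of the cortex marker list, was higher by 5.70 ± 0.20 log2 (SE, adjusted p = 5.7e-10), at a signal of 1831 ± 328 (SD, n = 3) against 174 ± 46 (SD, n = 3) in the endodermis. UGT84A1, a glucosyltransferase gene known to act on hydroxycinnamates, was higher by 5.31 ± 0.26 (SE), the peroxidase gene AT5G15180 by 5.41 ± 0.31 and the pectin methylesterase gene PMEPCRF by 5.19 ± 0.35. F6H1, a gene of scopoletin synthesis, was higher by 4.64 ± 0.26 (SE, adjusted p = 1.4e-08), and AT5G42250, AT1G13930, CYP71B34, AT5G59540 and AT3G45710 by 4.79 to 5.12. The most negative differences were those of AT3G12860 (-4.12), AT3G18600, an RNA helicase gene (-3.95), AT3G27200 (-3.80), AT2G40360 (-3.79) and AT5G51470 (-3.78).

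All 4 tested cortex markers were higher in the cortex: besides AT1G62510, AED3 by 3.98 ± 0.31, NPF6.4, a nitrate transporter gene, by 3.96 ± 0.17, and JKD, a zinc finger transcription factor gene, by 2.05 ± 0.29 (SE). The list was called by camera (adjusted p = 2.25e-05; adjusted p = 0.0067 with an estimated correlation), and 4 passed adjusted over the list alone. Both tested mitosis genes, for Aurora kinases, were lower (AUR2 -3.72 ± 0.20, AUR1 -1.92 ± 0.27, SE). Both tested xylem genes, PHV (-2.44) and LHW (-1.71), were also lower, and the stem cell gene BBM was lower (-1.73, adjusted p = 0.046). The BBM call ended without any single columella, cortex or endodermis array, or stele replicate 2 or 3 (adjusted p = 0.0512 to 0.149), and the PHV call without cortex replicate 1 or 2 (0.0859 and 0.0919). Both ended with a pseudocount of 64 (BBM -0.91, adjusted p = 0.0783; PHV -1.39, adjusted p = 0.0531). Adjusted over the list alone, 2, 2 and 1 were lower in these lists. F6H1 was the iron list's single higher gene, and PYE, an iron regulator gene, had a difference of -0.07. In total, 2145 probe sets were higher and 2355 lower in the cortex, and 722 were enriched; without both arrays in doubt, the counts were 2258, 2604 and 757, with 684 enriched probe sets shared. The median difference of all probe sets was -0.07 log2, and -0.22 under the deposited scaling, where 38.9% of called probe sets were higher against 47.7%.

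In the endodermis, dirigent and peroxidase genes, of families known to act on cell wall phenolics, were among the 10 enriched genes of largest difference. The dirigent genes AT4G13580 and AT2G39430 were higher by 6.61 ± 1.01 and 6.23 ± 0.43 log2 (SE), and the peroxidase genes AT5G66390 and AT1G44970 by 6.27 ± 1.23 and 5.88 ± 0.53. The protein kinase genes AT5G65530 and AT1G61590 were higher by 6.65 ± 0.76 and 6.10 ± 0.81, and AT1G43020, AT3G22620, AT1G30750 and AT1G71740 by 5.80 to 6.21. AT4G13580 had a signal of 11080 ± 1433 (SD, n = 3). Negative differences were smaller, from -2.97 for AT1G33590 and -2.80 for AT1G25400 to -2.67, -2.55 and -2.50 for AT2G16005, AT3G26440 and AT5G04970.

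All 3 tested endodermis markers were higher: SGN3, a receptor kinase gene of Casparian strip formation (4.55 ± 0.59, SE, adjusted p = 9.1e-05), BLJ, a zinc finger gene (3.38 ± 0.22), and EN7 (2.60 ± 0.25). The list was called by camera (adjusted p = 2.25e-05, and adjusted p = 0.010 with an estimated correlation), and 3 passed adjusted over the list alone. SGN3 was also called higher in the cortex, as 1 of the 3 there (2 of 3 without both arrays in doubt). The list was not called in the cortex (median 0.97, camera adjusted p = 0.115). All 4 cortex markers were also higher in the endodermis, JKD by 1.98 and AT1G62510 by 1.59, NPF6.4 by 1.35 and AED3 by 1.01 (camera adjusted p = 7.66e-05; adjusted p = 0.0070 with an estimated correlation). Adjusted over the list alone, 4 were higher, and 3 were called without both arrays in doubt. With a pseudocount of 64, AT1G62510 (0.59), NPF6.4 (0.51) and AED3 (0.46) were under the threshold, leaving JKD called. Of 2 tested stem cell genes, AGL42, a MADS-box gene expressed in the quiescent center, was higher by 1.13 ± 0.31 (SE, adjusted p = 0.021) and BBM had a difference of 0.52. The AGL42 call ended without endodermis replicate 1 or 3 (adjusted p = 0.103 and 0.111), and that of AED3, close to the threshold, without columella replicate 1, epidermis replicate 1 or 2, cortex replicate 2 or 3, stele replicate 3 or any endodermis array (log2 differences 0.87 to 1.13). The AGL42 call also ended with a pseudocount of 64 (0.50), a pseudocount of 1 (adjusted p = 0.0739) and no filter (0.111), and the AED3 call under the deposited scaling, with a pseudocount of 1, no filter, the 60th percentile and without both arrays in doubt. Of 2 tested mitosis genes, AUR2 was higher (1.50) and AUR1 had a difference of 0.21. In total, 1263 probe sets were higher and 552 lower in the endodermis, and 297 were enriched; without both arrays in doubt, the counts were 1460, 750 and 346, with 293 enriched probe sets shared. Leaving out endodermis replicate 3 left 191 enriched. The array labelled endodermis replicate 2 had an actin 3' to 5' signal ratio of 43.0, against 6.56 and 7.15 on the other endodermis arrays.

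In the population labelled epidermis and lateral root cap, both tested genes of the 10 in the root hair list were higher. EXPA18 and EXPA7, expansin genes of root hairs, were 4.28-fold and 3.90-fold higher (adjusted p = 0.0020 and 0.0037), and both passed adjusted over the list alone. Their log2 levels were 8.05 to 8.99 on the 3 epidermis arrays and as high on stele replicate 1 (8.05 and 8.55) and stele replicate 2 (8.56 and 8.16), against 5.78 and 5.86 on stele replicate 3, for EXPA7 and EXPA18 in turn. The most negative differences were those of AT3G32030 (-2.73), whose probe set can detect related genes, AT5G37540 (-2.61), AT1G62510 (-2.54), AT3G05150 (-2.39) and IRX15-L (-2.36). The cortex list (adjusted p = 0.00011; adjusted p = 0.0070 with an estimated correlation) and the endodermis list (adjusted p = 0.0095; adjusted p = 0.10 with an estimated correlation) were lower, with 4 of 4 and 3 of 3 members lower (3 of each without both arrays in doubt), and as many adjusted over the list alone. Without epidermis replicate 1, SGN3 (adjusted p = 0.217), AED3 (0.0761) and JKD (0.0543) lost their call, as did SGN3 without replicate 3 (0.197) and AED3 without replicate 2 (0.0566). As in the columella, the lower values of both lists here are in part the counterpart of higher values elsewhere. With a pseudocount of 64, AED3, JKD, BLJ and EN7 were under the threshold (-0.93 to -0.70). AED3, JKD and SGN3 lost their call with no filter or the 60th percentile (adjusted p = 0.0527 to 0.147), AED3 and SGN3 with a pseudocount of 1 (0.0932 and 0.0585) and AED3 without both arrays in doubt (-0.81). Of 2 tested mitosis genes, AUR1 was 2.14-fold higher and AUR2 did not pass (log2 0.78); AUR1 was under the log2 threshold without both arrays in doubt (0.77), without epidermis replicate 2 (0.85), with array weights (0.91) and with a pseudocount of 64 (0.77). As labelled, 1120 probe sets were higher, 984 lower and 0 enriched by limma, with 11 at an unadjusted p under 0.05 and 175 with array weights.

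Without both arrays in doubt, 1843 probe sets were higher, 1978 lower and 267 enriched in the epidermis. The enriched genes of largest difference were then AT3G49190 (5.07), AT3G06460 (4.86), AT5G58784 (4.69), AT1G71140 (4.41) and GH9C3 (3.81), followed by AT3G48460, AT2G37700, AT5G59240, ASPGB1 and AT2G43600 at 3.38 to 3.46. The most negative were AT4G11290, a peroxidase gene (-5.77), SBT4.12 (-4.45), AT4G13580 (-4.33), AT1G62480 (-4.32) and AT5G66390 (-4.30). These differences rest on the 2 remaining epidermis and 2 remaining stele arrays.

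In the population labelled stele, the vascular regulator gene LHW was higher by 1.46 ± 0.44 log2 (SE, adjusted p = 0.025), and PHV, a regulator of xylem patterning, had a difference of 1.20 (adjusted p = 0.30). The LHW call ended without stele replicate 2 or 3 (adjusted p = 0.128 and 0.181). Of 2 tested Aurora kinase genes, AUR1 was higher by 1.23 ± 0.27 (SE), but under the threshold with a pseudocount of 64 (0.89), and AUR2 did not pass (0.85). The most negative differences were those of AT2G43535 (-2.64), AT1G62510 (-2.62), AT3G32030 (-2.59), JAL33 (-2.58) and AT4G29700 (-2.52). The cortex list was lower, with 4 of 4 members lower (adjusted p = 2.25e-05; adjusted p = 0.0067 with an estimated correlation), and so was the endodermis list, with 1 of 3 members lower (adjusted p = 0.032; adjusted p = 0.17 with an estimated correlation; 0.107 without both arrays in doubt, and 0.00745 to 0.181 over all alternatives). Adjusted over the list alone, the counts were again 4 and 1, and without both arrays in doubt they were 3 and 1. Here too, the lower values of both lists are in part the counterpart of higher values elsewhere. JKD fell under the threshold without stele replicate 1 (-0.94), without both arrays in doubt (-0.86), with array weights (-0.84) and with a pseudocount of 64 (-0.72), and lost its call with no filter (adjusted p = 0.079) and the 60th percentile (0.0569). SGN3 lost its call without stele replicate 1 or 3 (adjusted p = 0.0884 and 0.0599). The single tested pericycle gene, LBD16, did not pass (-0.19). As labelled, 1048 probe sets were higher, 950 lower and 0 enriched by limma, with 3 at an unadjusted p under 0.05 and 288 with array weights. Of the called probe sets, 52.5% were higher, and 63.0% under the deposited scaling. AT2G43535 and JAL33 were no longer called without stele replicate 2 (adjusted p = 0.0556 and 0.0662) or replicate 3 (0.0863 for each, the highest over all alternatives).

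Without both arrays in doubt, 2057 probe sets were higher, 1748 lower and 448 enriched in the stele. PHV was then higher by 2.97 ± 0.26 log2 (SE, adjusted p = 2.9e-07), BBM, a regulator of root stem cells, by 2.41 ± 0.26 and LHW by 2.27 ± 0.27. The enriched genes of largest difference were scpl35, for a carboxypeptidase-like protein (4.83), MGL, for methionine gamma-lyase (4.59), AT3G51670 (4.46), AT4G20430 (4.27), AT5G24240 (4.16), AT1G28400 (4.14), TBL36 (4.08), AT3G15720 (3.77), SBTI1.1 (3.75) and AT3G28600 (3.63). AT3G19430 (-4.46), AT1G23160 (-4.28), AT5G51470 (-4.27), AT5G62340 (-4.27) and AT1G50060 (-4.15) were the most negative. All these values rest on stele replicates 2 and 3 and epidermis replicates 1 and 3. The arrays left out were chosen because they were unlike their own label. Leaving them out lowers the spread within both labels, so SE and p-values of this fit understate the spread as labelled.

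**Figure D3:**
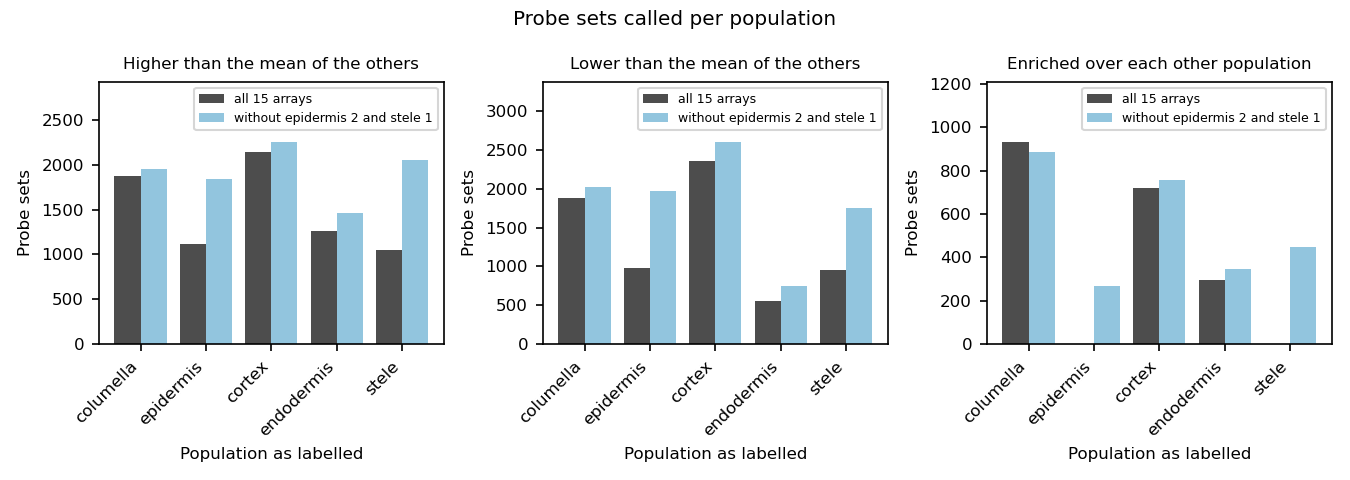
Number of probe sets called higher, lower and enriched in each population as labelled, with all 15 arrays and without the arrays labelled epidermis replicate 2 and stele replicate 1. Enriched counts go from 0 to 267 in the epidermis and from 0 to 448 in the stele when both are left out.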

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

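The tests in this part were chosen after the result was seen. The first pair of bounds on the shares below was also set after that, but before those shares were seen. No probe set was enriched in the populations labelled epidermis and stele, and 1 epidermis and 2 stele arrays lay nearest to an array of the other population. Stele replicate 2 lay nearest to epidermis replicate 2 (r = 0.973) but nearly as close to its own population (0.962). Probe sets enriched in the epidermis without both arrays reached a median of -1.70% of the epidermis level (95% bootstrap interval -3.02 to 0.0542, 267 probe sets) on the array labelled epidermis replicate 2, where stele-enriched ones reached 81.8% of the stele level (448 probe sets). On the array labelled stele replicate 1, stele-enriched probe sets reached 0.214% and epidermis-enriched ones 65.7% (60.2 to 72.6). The own shares, with upper quartiles of 8.13% and 8.89%, argue against a mixture of both RNAs in which the labelled population supplied over 25%.

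An exchange of the 2 labels stays open by the bounds on shares below, but other values go with it. Epidermis replicate 2 correlated at 0.97 and 0.95 with stele replicates 2 and 3 but at 0.83 and 0.82 with its own label. Stele replicate 1 correlated at 0.96 and 0.97 with epidermis replicates 1 and 3 but at 0.84 and 0.85 with its own label. Without both arrays, correlations ran from 0.947 to 0.984 within populations and from 0.669 to 0.874 between them. The values of both arrays with the other label thus lie in the range within populations. Those with their own label lie in the range between populations. A fit with the 2 labels exchanged was not run. The 2 tested root hair genes did not separate the labels. On epidermis replicate 2, EXPA7 and EXPA18 were at 8.41 and 8.63 log2, close to the other epidermis arrays, but stele replicate 2 had 8.56 and 8.16 and stele replicate 3 had 5.78 and 5.86. The xylem genes PHV and LHW and the root cap gene RCPG went with an exchange (the label's other arrays in parentheses). On epidermis replicate 2 PHV was at 9.11 (others 5.56 and 5.37), LHW at 9.98 (8.60 and 7.87) and RCPG at 4.82 (9.19 and 9.61). On stele replicate 1 PHV was at 4.52 (others 8.59 and 9.14), LHW at 8.32 (10.06 and 10.53) and RCPG at 8.92 (4.59 and 6.86). The first bounds, 25% for the own and 75% for the other label, were set before the shares were seen; they would have excluded an exchange, since 65.7% is under 75%, and left a mixture undecided. They were replaced after that, because 1 of 9 held-out arrays of the other populations, endodermis replicate 2, reached only 68.7% of its own population's level (64.1 to 74.6; range over the 9 arrays 68.7 to 113%), and a mixture was then judged by the 25% bound alone. Against that range epidermis replicate 2 lies inside and stele replicate 1 below it, with overlapping intervals, so by this rule the exchange is neither met nor excluded. The low end is 1 array with an actin 3' to 5' ratio of 43.0. Without it, the lowest is cortex replicate 1 at 83.7% (81.7 to 86.1), and the rule would exclude an exchange. Held-out shares were set against all other populations, and those of the arrays in doubt against epidermis or stele alone, so the measures differ. The intervals resample probe sets of 1 array and do not measure spread between arrays. In all, 3 sets of bounds were tried; bounds of 10% and 50%, chosen with the shares in view and not used, would have favoured an exchange. Degraded RNA stays open for epidermis replicate 2. Stele-enriched probe sets were 1.40 log2 higher on epidermis replicate 2 than on the other epidermis arrays (447 of 448 above 0), which a loss of signal alone would not give. The actin 3' to 5' ratio was however 28.3 there, against 9.40 and 9.47 on the other epidermis arrays and 22.0 and 22.96 on stele replicates 2 and 3, and its GAPDH ratio of 15.2 was the highest of the 15 arrays, while its ubiquitin ratio of 4.33 was below those of the other epidermis arrays (5.39 and 4.46). On stele replicate 1 degraded RNA is argued against: epidermis-enriched probe sets were 1.26 log2 higher than on stele replicates 2 and 3 (261 of 267 above 0), and its actin ratio of 16.9 and GAPDH ratio of 9.20 were below theirs (GAPDH 13.5 and 12.8), though its ubiquitin ratio of 4.79 was above theirs (3.44 each). The signal of a 25S rRNA probe set was 784 on stele replicate 1 against 9172 and 10158 on stele replicates 2 and 3, and 6430 on epidermis replicate 2 against 2291 and 1515 on the other epidermis arrays, so on this measure too each array lay closer to the other label; whether RNA quality or the label sets it was not tested. A difference between seedlings or sorts was not tested.

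A control probe set for a sequence named U12639 had a mean signal of 13314 ± 1348 (SD, n = 3) in the columella and at most 21.7 on every other array. It stood out as a signal in data that the comparisons left out. Stronger hybridization of the columella arrays as a whole is argued against, since the hybridization control cre was up to 2.08 times brighter on another array than on the dimmest columella array. A sequence carried by the columella marker line may be a source, but with 1 marker line per population, line and cell type cannot be told apart.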

How the results depend on the processing

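Fits without both arrays in doubt were chosen after seeing the data. No result reversed. The settings were run for 116 pairs of a called gene and a population (74 genes): those named for the largest enriched or most negative differences and all called members of the fixed lists. Of these, 25 lost their call under at least 1 setting, leave-one-out included, and 0 changed direction. The losses, with a pair counted under each setting, were 19 with a pseudocount of 64, 5 with a pseudocount of 1, 7 with no filter, 6 at the 60th percentile, 4 with array weights, 4 without both arrays in doubt and 2 under the deposited scaling. Without 1 array, 18 pairs lost their call, in 50 combinations of pair and array; of those named for the largest differences, AT2G43535 and JAL33 did so in the stele without stele replicate 2 (adjusted p = 0.0556 and 0.0662) or replicate 3 (0.0863 each). Under the deposited scaling and without the variance trend no count moved by over 1.5 times. With a pseudocount of 64, which shrinks differences of dim probe sets, 1211 were lower in the columella, 645 higher and 499 lower in the epidermis, 1401 lower in the cortex, 317 lower in the endodermis, and 627 higher and 531 lower in the stele. Enriched probe sets in the endodermis numbered 187 with no filter and 193 at the 60th percentile; the cause was not tested. Array weights gave 1706 higher, 1835 lower and 175 enriched in the epidermis and 1877, 1571 and 288 in the stele. Without both arrays in doubt these were 1843, 1978 and 267, and 2057, 1748 and 448. In the stele, 1 list in place of 2 was called with a pseudocount of 1, no filter, the 60th percentile, array weights and without both arrays in doubt. With an estimated correlation, 1 list was called in each of the columella, epidermis and stele. Leaving out 1 array at a time gave 697 (without epidermis replicate 1) to 1732 (without replicate 2) lower and 0 to 17 enriched in the epidermis, 662 (without stele replicate 2) to 1793 (without replicate 1) higher, 758 to 1436 lower (without replicate 1) and 0 to 3 enriched in the stele, 191 (without replicate 3) to 347 enriched in the endodermis, and 1 to 2 lists in the stele (1 without endodermis replicate 2, or stele replicate 1 or 3). Signal near background limits calls of dim probe sets.

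With the replicate number as a block, 10575 probe sets differed among the populations, against 10660, and no count of calls moved by over 1.5 times. Over 30 pairs of arrays with the same number, correlations of deviations ran from -0.52 to 0.72 with a median of -0.01, and 6 were over 0.1. The extremes, -0.52, 0.59 and 0.72, were all between epidermis and stele arrays, whose population means include the arrays in doubt. No common pairing by number was seen. Deviations cancel out within each population, so these correlations cannot exclude a shared batch.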

Other observations

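The family lists and all tests in this part were chosen after seeing the data. UDP-glucosyltransferase genes, a family that attaches sugars to small molecules, were higher in the cortex: 20 of 38 tested members were higher and 1 lower, with a median of 1.07 log2 (camera adjusted p = 0.0021; adjusted p = 0.44 with an estimated correlation; median 0.92 under the deposited scaling). UGT84A1 (5.31), UGT76E12 (4.47), UGT71C1 (3.06) and UGT73B1 (2.83) had the largest differences, and UGT73C7 was lower (-1.18). In the endodermis, UGT72E3 (4.14) and UGT71C3 (3.00) were higher, but the family was not called there (adjusted p = 0.75, median -0.23), with 8 members higher, 2 lower and 28 not passing. TBL30 (4.46) and TBL19 (4.20), of a family known to acetylate cell wall polysaccharides, were higher in the endodermis, and TBL41 (4.49) in the cortex; the family was not called by camera in either (adjusted p = 0.21 and 0.11).

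Of 24 families and groups, in 120 tests, others were called at an adjusted p of 0.030 to 0.040 and none of them with an estimated correlation (adjusted p of 0.44 to 0.62). Tetraspanin genes were higher in the endodermis, with 3 of 9 called (TET6 1.89, TET8 1.42, TET5 1.26). PRA genes were higher there, with 2 of 9 called, and lower in the epidermis and the stele as labelled, with 2 of 9 called in each; without both arrays in doubt these calls ended (adjusted p = 0.059 to 0.15), while the medians went from 0.74 to 0.73 in the endodermis, -0.45 to -0.38 in the epidermis and -0.38 to -0.50 in the stele. In the stele, UGT genes were lower, with 6 of 38 lower and 2 higher, and genes with a CYP symbol were lower, with 5 of 13 lower. This list was grouped by symbol alone and mixes cytochrome P450 genes with the cyclophilin genes CYP71 (0.88) and CYP59 (0.36), which were not among those lower. It was not called under the deposited scaling (adjusted p = 0.059) or without both arrays in doubt (adjusted p = 0.059, median -1.07 against -0.71).

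Plastid-encoded genes were lower in the columella, with 24 of 67 tested members lower and 0 higher (median -0.89 log2, camera adjusted p = 5.27e-05; adjusted p = 0.79 with an estimated correlation). They were higher in the population labelled stele, with 20 of 67 higher and 0 lower (median 0.65, adjusted p = 6.97e-07; adjusted p = 0.65 with an estimated correlation). Among them, accD (-2.08), matK (-1.97) and rps4 (-1.84) were lower in the columella and rpoC1 (2.24), rpl22 (2.04) and rpl36 (1.96) higher in the stele. Both directions held under the deposited scaling (medians -0.85 and 0.75). The median deviation of these genes was 0.27, 0.93 and 0.36 on the 3 stele arrays, -0.51, -0.71 and -0.74 on the columella arrays, and 0.86 on the array labelled epidermis replicate 2. Stele replicates 2 and 3 and epidermis replicate 2 also had the highest median signals of the 15 arrays (77.3, 76.3 and 80.9, against at most 65.1), with actin 3' to 5' ratios of 22.0, 22.96 and 28.3. The array with the highest actin ratio, endodermis replicate 2 (43.0), had a plastid median of -0.46, the lowest of its population.

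Other ways of dividing the 15 arrays into 5 groups of 3 were tried, 100 splits with the real one included. The F test's 10660 probe sets were reached by 1 split, the real one, and the highest other gave 1670, so a chance division of these arrays rarely gives such a count. No value under 1 of 100 could be reached. Splits of arrays that may be technical replicates show how alike the arrays of a population were, and cannot speak to biological replication. The same 1 of 100 held for called probe sets in the columella (3766, highest other 231), cortex (4500, highest other 3253), endodermis (1815, highest other 3) and stele (1998, highest other 28), and for enriched ones in the columella (932, highest other 0), cortex (722, highest other 561) and endodermis (297, highest other 0). For the epidermis, 2 of 100 splits reached the 2104 called probe sets, and the higher one, 3482, put the 3 cortex arrays together in that slot, as did the highest other splits for the cortex, so these counts reflect the likeness of the cortex arrays. Chance was not excluded for the 0 enriched in the epidermis and stele, reached by 100 of 100 splits because no count is below 0 (highest other 567 and 0). Nor was it excluded for the numbers of called lists: 14 of 100 splits reached the 2 in the columella, 12 the 2 in the epidermis, 34 the 1 in the cortex, 15 the 2 in the endodermis and 11 the 2 in the stele, with 2 the highest other in each.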
